A study of Homo sapiens with 36 samples.

How the data were processed

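Gene expression was measured on 36 Affymetrix arrays of the human HG-U133 Plus 2.0 type, 3 for each of 12 groups formed by 6 cancer cell lines and 2 cell fractions. Per the labels' protocols, cells were grown for 24 hours on porous filters, and the material on the lower side of the filter (pseudopods) and on the upper side (cell bodies) was scraped off separately. U87, U251 and HT1080 were grown in DMEM and DU145, MDA231 and MDA435 in RPMI-1640, per the labels, so the medium differs between lines and not between the fractions of a line. Per the labels, 100 ng of total RNA was amplified and biotin-labelled in 2 cycles.

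The deposited values are linear intensity values, 1 column per array, from 0 to 9883.2 over 54593 probe sets. The submitters' processing notes name RMA and Partek without a role or version. RMA gives log2 values, and the deposited intensity values are not on that scale. Their mean after leaving out 2% of probe sets at each end lies between 149.18 and 149.59 in all arrays, which is the result of scaling each array to a common mean, and their medians lie between 18.2 and 30.6. The program that made the intensity values is not given in the sources used here. Array control probe sets were not analysed here (0 in the table), so neither 3-prime to 5-prime ratios nor spike-in levels were used.

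The design fixed before the data were examined assumed log2 values. Since the deposited intensity values were linear, log2(intensity + 16) was computed first. A log2 change and the fold made from it are on that scale, which understates the change of dim genes, so folds are not ratios of the intensities printed beside them. Of the probe sets, 41074 carry 1 gene symbol in the platform annotation, 1798 carry several and 11721 carry none; 41020 of those with 1 symbol were brought to current symbols through their Entrez numbers in the RefSeq gene table of GRCh38.p14, from which no coordinates are given. Probe sets with several or no symbols were not named. For each of 19775 genes the probe set with the highest mean over all arrays was used, and 15294 genes whose highest group mean reached the median of all values (24.4 intensity units) were tested. Values of a named gene are those of that probe set.

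Tests used limma 3.58.1 in R 4.3.3, with 12 group means (24 residual degrees of freedom) and an empirical Bayes estimate of the spread shared by all arrays. Contrasts were pseudopod minus cell body averaged over the 6 lines, the same within each line, and a moderated F test of the 5 differences between lines. A second fit took the 6 line differences as the units. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 29 gene lists, fixed before the data were examined, were tested on the averaged contrast with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes. Array statistics were compared between fractions with a two-sided permutation test (100000 resamples of the fraction labels within lines), adjusted over a family of 4 measures. Figures were drawn in Python 3.11.15.

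The named genes follow a rule fixed before the data were examined. For the averaged contrast these are the 12 largest rises and 12 largest falls among called genes with 1 sign in all 6 lines; for a line, the 4 largest rises and falls among called genes whose pseudopod and cell body arrays do not overlap; for the interaction, the 6 largest F values; for each list, up to 4 called members with the largest change or, where none was called, the 1 member with the largest change; and for each line, up to 3 lineage markers that differ most from the other lines. With the lines as units, the 10 largest called changes were named. AHNAK, S100A11, EIF4E, SEPTIN9, MALAT1, NEAT1, RAB13, NET1, ACTB and GAPDH were fixed by name; NEAT1 was not analysed here. Y-linked genes and XIST were never named. Other members of the lists are named where they passed or failed the test against the rest of their list, and these were chosen after their values were seen.

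The fits were tested on simulated data made from the measured line means and gene spreads, with 200 of 15294 genes changed. For the averaged contrast, 92.5% of the genes changed 1.5-fold and 98.5% of those changed 2-fold were recovered, with 7 false calls. In U87 alone these shares were 26.9% and 76.1%, with 6 false calls, and for an interaction in which only U87 changed they were 2.99% and 37.3%, with 3 false calls. All simulated arrays of a gene had the same spread. In the data the residual spread of pseudopod arrays ran from 0.22 in U251 to 0.42 in MDA435, with 0.37 in U87. The false calls expected in a line with a larger spread are therefore not known from this simulation. In a simulation of 29 lists over 15294 genes, the 1 shifted list was called and 0 of 28 unchanged lists were. The simulated genes varied independently, whereas the estimated correlation was 0.78 in the ribosomal list and 0.52 in the ER chaperone list. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes.

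Alternatives fixed before the data were examined changed the scaling (equal array medians, quantile normalization), the filter on dim genes, the choice among probe sets, the prior and the array weights, added the replicate number as a block, asked for at least 1.5-fold, fitted each line alone, and left out each array or line. Pseudocounts of 1 and 64, fits without MDA231 and MDA435 or without DU145, MDA231 and MDA435, an epithelial covariate (the mean log2 value of CDH1 and EPCAM, centred within groups, with its own slope in DU145, MDA231 and MDA435) and the fit without U87 pseudopod replicate 3 were chosen after seeing the data. Being centred within groups, the covariate leaves every pseudopod change as it was and alters only the spread, which all lines share. It does not correct the changes for epithelial genes. The number of arrays limits the precision, and the labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.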

Results

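Pseudopod and cell body fractions of 6 human cancer cell lines were profiled on 36 arrays, with 3 arrays per line and fraction. U87 and U251 are glioblastoma lines, HT1080 is a fibrosarcoma line, DU145 a prostate carcinoma line and MDA231 a breast carcinoma line. MDA435 is a line described as breast cancer whose origin was long disputed because of its melanocytic gene expression. The design asks how the RNA of the protruding part of metastatic cells differs from that of the cell body. Median intensity was 23.0 ± 2.49 in the pseudopod arrays and 25.8 ± 2.29 in the cell body arrays (SD, n = 18 each; difference -2.71, two-sided permutation test, p = 0.00107, adjusted p = 0.00214 over 4 measures). The share of probe sets at or below 16 intensity units was 42.8% in pseudopods and 40.3% in cell bodies (adjusted p = 0.00214 by the same permutation test), and the 99th percentile was 3045 against 2810 (adjusted p = 0.0206). The highest intensity was 5963 in pseudopods and 5590 in cell bodies (adjusted p = 0.272, permutation test).

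Lineage genes differed between the lines. KRT18, an epithelial keratin, stood at 6.17 ± 0.82 intensity units in U87 against 2410 ± 836 in the other lines (SD, n = 6 and 30), and COL1A2, a collagen chain, at 3454 against 241. In U251 the neural membrane protein gene GPM6A (2978 against 26.1), PDGFRA (2223 against 28.4) and the neural transcription factor gene SOX2 (1823 against 57.7) were highest. DU145 had high KRT7 (2341 against 165) and KRT19 (2932 against 498). MDA435 had high S100B (2402 against 7.86) and SOX10 (1468 against 16.4), both expressed in glial and melanocytic cells, and its LOX was at 4.90 against 795 elsewhere. MDA231 also had much KRT19 (2152 against 654), though less than DU145. HT1080 had COL6A3 at 2506 against 745, though U87 had 3506. All of these differences were called (limma, highest adjusted p = 1.87e-09 for KRT19 in MDA231), and 0 of the 36 arrays correlated best with an array of another line.

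Epithelial genes differed between replicate arrays of the same group. CDH1, which encodes E-cadherin, was at 1299 in MDA231 pseudopod replicate 3 and 1778 in cell body replicate 2, against at most 13.7 in the other 4 MDA231 arrays. In MDA435 its intensities were 2073, 922 and 33.2 in pseudopod replicates 1, 2 and 3 and 32.8, 1044 and 2463 in cell body replicates 1, 2 and 3. DU145 ranged from 319 in pseudopod replicate 1 to 2237 in cell body replicate 1. EPCAM, an epithelial surface antigen, went the same way, with 3019 in MDA231 pseudopod replicate 3 and 3336 in cell body replicate 2 against at most 618 in the other 4. SOX10 in MDA435 was at 2002 in pseudopod replicate 3 and 2450 in cell body replicate 1, and from 884 to 1267 in the other 4 arrays. KRT19 in MDA231 was at 1793 in pseudopod replicate 3 and 1419 in cell body replicate 2, and from 1799 to 2998 in the other 4, and KRT18 at 3792 and 3200 against 2193 to 3023. In MDA435 pseudopod replicates 1, 2 and 3 KRT19 was at 785, 429 and 1.1 and KRT18 at 3303, 3063 and 1114, and in cell body replicates 1, 2 and 3 KRT19 was at 0.50, 204 and 530 and KRT18 at 839, 1799 and 3367. The residual spread on the log2 scale was 0.41 in the MDA231 pseudopod arrays and 0.42 in those of MDA435, against 0.37 in U87, 0.25 in DU145, 0.23 in HT1080 and 0.22 in U251, so a large spread also occurred in U87, where CDH1 averaged 1.55.

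**Figure D1:**
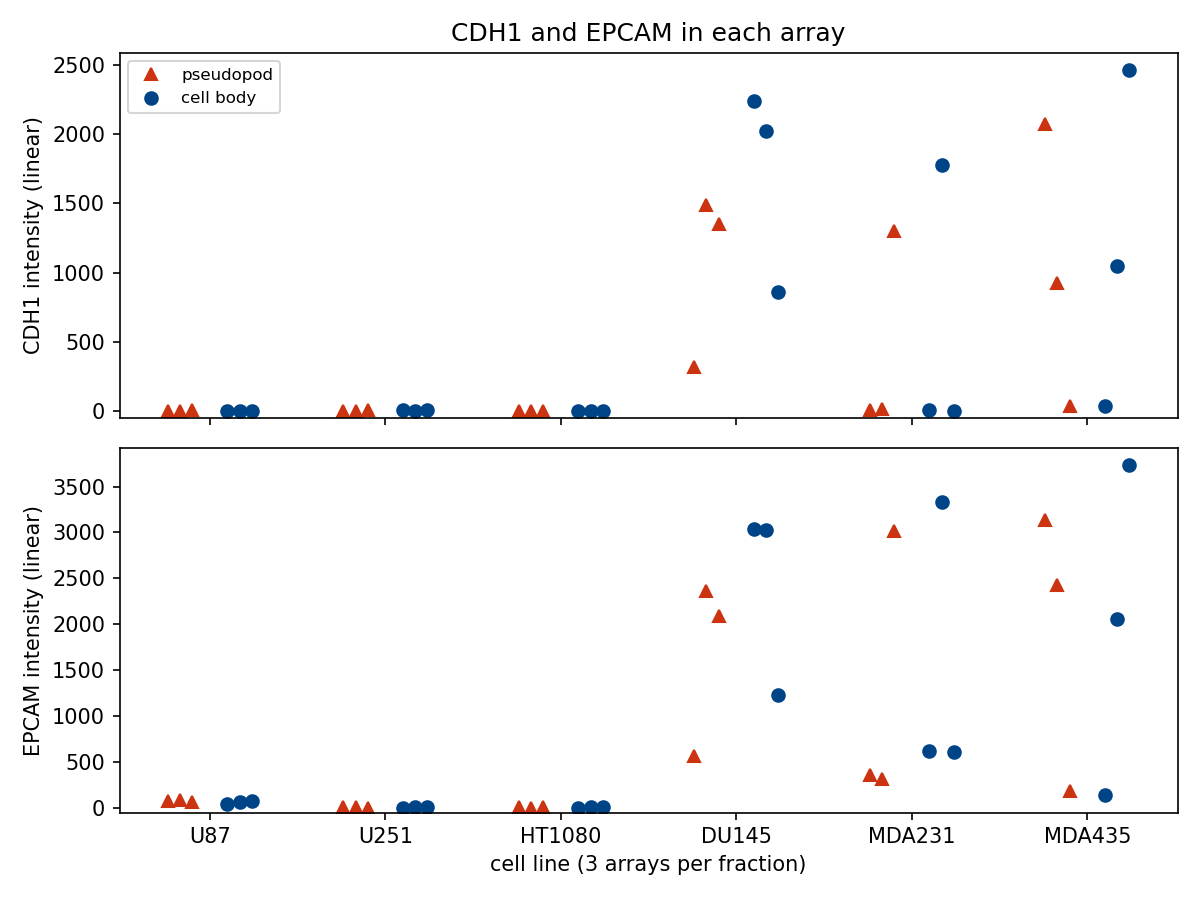
Intensity (linear scale) of CDH1 (top) and EPCAM (bottom) in each of the 36 arrays, by cell line, with triangles for pseudopod and circles for cell body arrays. CDH1 in MDA435 runs from 32.8 to 2463 within 1 fraction.

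Averaged over the 6 lines, the largest change was that of RNA45SN5, the precursor of ribosomal RNA. It fell by 3.25 ± 0.23 on the log2 scale (SE; 9.51-fold lower; limma, adjusted p = 3.76e-12), from 599 ± 371 intensity units in cell bodies to 60.0 ± 92.8 in pseudopods (SD, n = 18 each), in 6 of 6 lines. ESYT1, which tethers the endoplasmic reticulum (ER) to the plasma membrane, was lower by 3.88-fold, and SERPINH1, the ER chaperone of collagen, by 3.57-fold (log2 changes -1.95 ± 0.16 and -1.83 ± 0.12). The risers changed by a little over 2-fold at most, among them HINT3, a nucleotide hydrolase gene (1.15 ± 0.15, 2.21-fold), ROMO1, a mitochondrial inner membrane protein (1.06 ± 0.12), and SEM1, a proteasome subunit (1.04 ± 0.10, from 1247 to 2625 intensity units). Of 15294 genes, 4549 were higher and 3188 lower in pseudopods; at least 2-fold changes numbered 7 upward and 658 downward.

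The other named risers were CENPH, a kinetochore protein gene (1.08), POLD4, a subunit of DNA polymerase delta (1.05), NUDT14 (1.01), BCL7C (0.97), EIF4EBP1, a repressor of translation initiation (0.93), GRWD1 (0.92), the kinase gene MAPK3 (0.91) and the cell cycle transcription factor gene MYBL2 (0.91), with standard errors from 0.08 to 0.20 and the highest adjusted p at 8.14e-05 for POLD4. RPL7AP10 rose by 1.12, but it is a pseudogene of RPL7A and its probe set may hybridise with that gene. The other named fallers included STT3A, the catalytic subunit that attaches glycans to nascent proteins (-1.77), ALG1, an ER mannosyltransferase (-1.76), HSPA13, an ER-associated HSP70 (-1.78), CCPG1, an ER-phagy receptor (-1.83), IL1RAP, a cytokine receptor subunit (-1.83), RNF149, a membrane ubiquitin ligase (-1.76), and B4GAT1, a Golgi glycosyltransferase (-1.78), whose other probe set changed by 0.21. SNORA21, a small nucleolar RNA, fell by 1.78, from 100.3 to 18.1 intensity units, and FRG1BP, a pseudogene transcript, by 1.73. Among genes fixed by name, AHNAK, a giant scaffold protein gene, fell by 1.52 ± 0.13 (1 of its 3 probe sets changed by 0.44 instead), and the nuclear RNA MALAT1 fell by 0.69 ± 0.14 (12 of 12 probe sets lower). S100A11 rose by 0.77 ± 0.11, RAB13 by 0.69 ± 0.09, NET1 by 0.51 ± 0.10 and EIF4E by 0.24 ± 0.08 (adjusted p = 0.0204, and 0.0900 with quantile normalization). SEPTIN9 (0.17, adjusted p = 0.114) and ACTB (0.14, adjusted p = 0.121) did not pass, but passed with equal array medians (adjusted p = 0.027 and 0.0142). GAPDH (0.10, adjusted p = 0.382) did not pass, and its sign turned with quantile normalization (-0.02). The split between higher and lower calls depended on the scaling: 58.8% of calls were higher as deposited, 71.7% with equal array medians and 65.2% with quantile normalization, while the median change of all genes moved from 0.05 to 0.15 and 0.09.

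**Figure D2:**
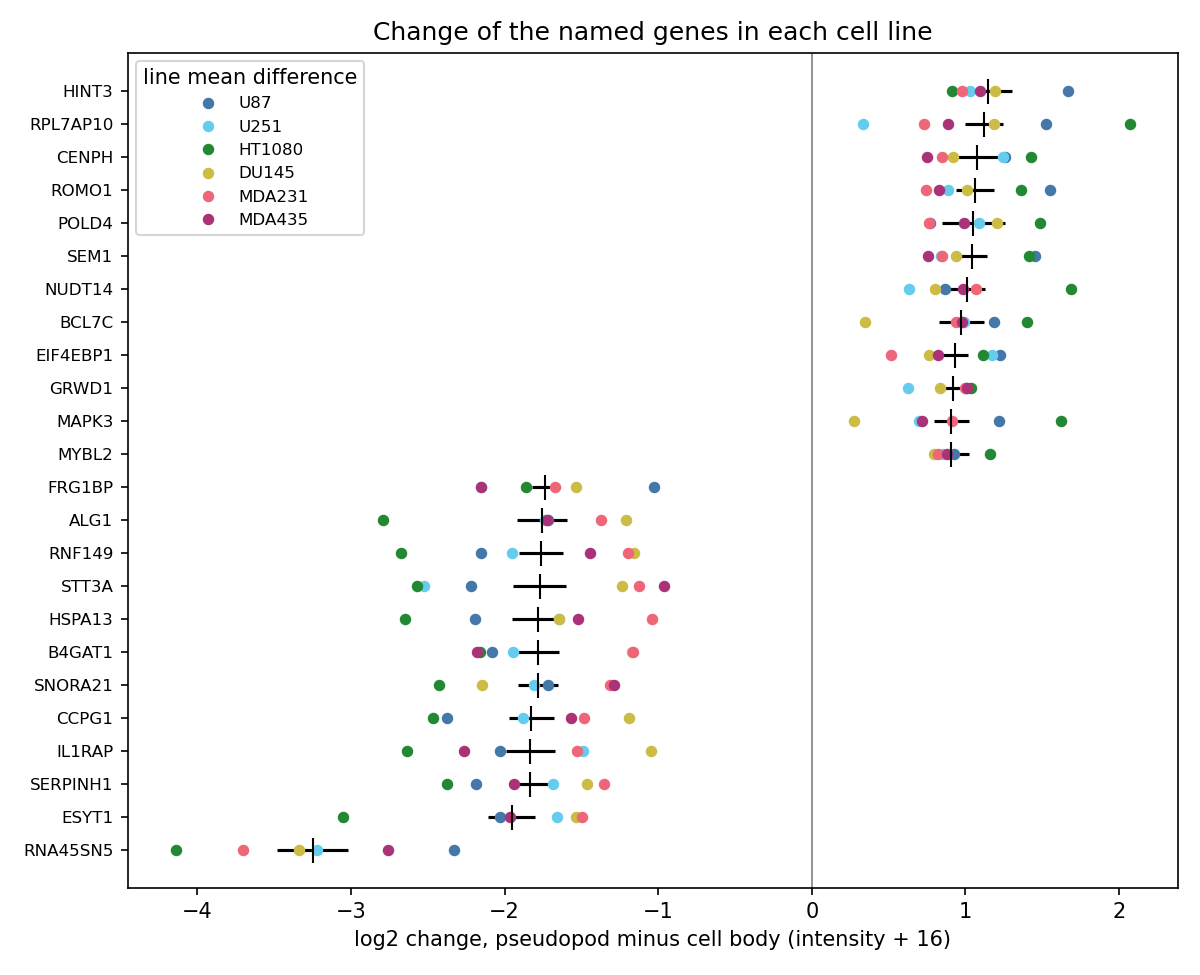
Log2 change (pseudopod minus cell body, on intensity + 16) of the 24 genes named for the averaged contrast. Coloured points are the 6 line differences, and the black mark is their mean with its SE as a bar; RNA45SN5 lies lowest, at -3.25.

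Genes of the secretory pathway and the cell surface fell together. Of 40 tested genes for extracellular matrix and its proteases, 37 fell and 0 rose, with a median change of -0.97 (SD over genes 0.39). Examples are LOXL2, which cross-links collagen (-1.52 ± 0.17), the matrix glycoprotein gene THBS1 (-1.51 ± 0.14), and the collagen chain genes COL6A2 (-1.46 ± 0.21) and COL6A1 (-1.37 ± 0.18; 0.13 without the probe sets that the array design marks as shared between transcripts, adjusted p = 0.336). Camera with the preset correlation called the list (adjusted p = 2.21e-16), with adjusted p = 0.225 with an estimated correlation. Of 27 ER chaperone and folding genes, 24 fell and 3 rose, median -0.97, among them HSP90B1 (-1.48 ± 0.22), SEL1L (-1.43 ± 0.13), DNAJB11 (-1.39 ± 0.14) and PDIA4 (-1.38 ± 0.20) (camera adjusted p = 2.84e-11; adjusted p = 0.28 with an estimated correlation). The 3 that rose were ATF4 (0.33) and DDIT3 (0.32), which encode transcription factors, and SEC61B (0.29), a tail-anchored subunit of the translocon. Of 33 integrin and focal adhesion genes, 17 fell and 6 rose (camera adjusted p = 0.00159; adjusted p = 0.28 with an estimated correlation). The fallers include membrane proteins, such as CD151 (-1.38), ITGAV (-1.33), ITGA2 (-1.33) and SDC4 (-1.27), and the 6 risers encode proteins on the cytoplasmic side of adhesions: PARVA (0.83), ZYX (0.50), LPP (0.44), PXN (0.34), TLN1 (0.26) and ILK (0.24). VCL, which encodes the cytoplasmic adhesion protein vinculin, fell by 0.81 ± 0.07 all the same (adjusted p = 1.38e-10). Of 18 mesenchymal markers, 12 fell and 1 rose, with FBN1 (-1.27), CDH2 (-1.17), LOX (-1.09) and COL5A2 (-0.97) falling most (camera adjusted p = 0.00319; adjusted p = 0.28 with an estimated correlation).

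Genes for respiration, protein synthesis and chromatin rose by smaller amounts. Of 61 nuclear-encoded respiratory chain genes, 54 rose and 0 fell, median 0.37, including the ATP synthase subunit genes ATP5F1D (0.84 ± 0.09) and ATP5ME (0.80 ± 0.09) and COX6B1 (0.73 ± 0.08) (camera adjusted p = 2.44e-12; adjusted p = 0.28 with an estimated correlation). Cytosolic ribosomal protein genes rose in 36 of 50 cases and fell in 0, with RPL11 (0.82 ± 0.08) and RPL36 (0.78 ± 0.07) rising most (camera adjusted p = 5.35e-07; adjusted p = 0.508 with an estimated correlation). Translation factors rose in 31 of 37 cases, led by EIF4EBP1 and EIF4EBP2 (0.63 ± 0.06), followed by EIF3G (0.56) and EIF5A (0.53; adjusted p = 0.0551 with the mean of all probe sets) (camera adjusted p = 4.29e-07; adjusted p = 0.28 with an estimated correlation). Among 13 core histone genes 11 rose, led by H1-2 (0.65) and H2BC12 (0.57) (camera adjusted p = 0.002; adjusted p = 0.225 with an estimated correlation). DNA replication genes rose in 16 of 26 cases, with GINS2 at 0.65 (adjusted p = 0.171 without the marked probe sets), CDT1 at 0.56, PRIM1 at 0.38 and MCM4 at 0.43 (-0.02 without the marked probe sets) (camera adjusted p = 0.00319; adjusted p = 0.508 with an estimated correlation).

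Cytoskeletal genes changed by less and not all 1 way. Of 28 genes for the Arp2/3 complex and actin nucleation, 15 rose and 1 fell: BRK1 (0.56), ARPC3 (0.51) and ARPC1A (0.49) rose, and the formin gene DIAPH1 fell by 0.62. Of 39 genes for actin filament binding, 19 rose and 3 fell, including TPM4 (0.74), CNN2 (0.61) and MYL9 (0.48) upward and ACTN4 (-0.54) downward. Among 37 microtubule genes 21 rose and 3 fell, with DYNLT1 (0.60) and KIF1C (0.57) higher and the dynein heavy chain gene DYNC1H1 (-0.72) and CLIP1 (-0.61) lower. Camera called these lists at adjusted p = 0.00613, 0.00714 and 0.0108; each had adjusted p = 0.28 with an estimated correlation, and with quantile normalization the values were 0.0617, 0.185 and 0.101, so the calls ended. Of 14 RNAs described elsewhere as localised to protrusions, 8 rose, among them RASSF3 (0.70), RAB13, KIF1C and NET1, and 2 fell, DDR2 (-0.77) and P4HB (-0.97), which encode a membrane receptor and an ER enzyme; the list was not called (camera adjusted p = 0.0649).

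The remaining lists were not called by camera on the averaged contrast. Septins rose in 4 of 7 cases, with SEPTIN6 (0.39; adjusted p = 0.684 without the marked probe sets) and SEPTIN10 (0.37) highest (camera adjusted p = 0.0703, and 0.0486 with array weights). In the S100, annexin and AHNAK list 9 of 23 rose, with S100A11 and ANXA11 (0.56) highest, and 2 fell, AHNAK and AHNAK2 (adjusted p = 0.213; ANXA11 had adjusted p = 0.62 without the marked probe sets). Mitochondrially encoded genes fell in 3 of 7 cases, COX3 (-0.69), ND2 (-0.45) and ND6 (-0.44), and rose in 0, against the nuclear-encoded respiratory genes (adjusted p = 0.0703, and 0.00146 with quantile normalization). Of 16 cholesterol synthesis genes 8 fell and 4 rose, and the 4 largest changes were in the ER membrane enzyme genes SQLE (-1.51), SC5D (-1.22), MSMO1 (-1.09) and DHCR7 (-1.02) (adjusted p = 0.0813). Among 34 hypoxia and glycolysis genes 8 rose and 9 fell, the largest falls being the ER collagen hydroxylase genes P4HA2 (-1.62) and P4HA1 (-1.29) and the glucose transporter genes SLC2A3 (-1.26) and SLC2A1 (-1.02) (adjusted p = 0.335; the median of 0.02 differs in sign from the mean of -0.17 and the test; with quantile normalization the median was -0.02 and adjusted p = 0.0325). Of 23 EMT genes 10 fell, including MET (-1.29) and TGFBR1 (-1.03), and 3 rose (adjusted p = 0.058, and 0.0272 with equal array medians). Nuclear-retained RNAs gave 4 falls, led by FTX (-0.87), and 2 rises of 10 (adjusted p = 0.359), and splicing factors 7 falls, led by CLK1 (-0.75), and 15 rises of 41 (adjusted p = 0.561, and 0.0204 with the mean of all probe sets, where the median turned to -0.07). Mitotic genes gave 9 rises and 4 falls of 31, with UBE2C at 0.46 and ASPM (-0.92), ANLN (-0.82) and CENPF (-0.61) lower (adjusted p = 0.668). Immediate early genes gave 5 rises and 2 falls of 26, with CCN2 (-1.18) and CCN1, both secreted proteins, falling and JUND (0.48) and KLF2 (0.43; -0.02 without the marked probe sets) rising (adjusted p = 0.668). Heat shock genes rose in 6 of 15 cases, led by HSPE1 (0.55) (adjusted p = 0.117). Interferon response genes gave 3 rises and 4 falls of 27, the falls being HLA-B (-0.93), IFI6 (-0.87), BST2 (-0.77) and HLA-C (-0.76) (adjusted p = 0.55; the median of 0.03 differs in sign from the mean of -0.06 and the test). Epithelial markers gave 2 rises, KRT7 (0.33) and KRT18 (0.31), and 1 fall, CLDN4 (-0.56), of 17 (adjusted p = 0.735). Melanocytic markers gave 1 rise, RAB27A (0.31), and 3 falls of 12, GPM6B (-0.68), PMEL (-0.40) and TYR (-0.20) (adjusted p = 0.393). Glial and neural markers fell in 6 of 18 cases, led by SLC1A3 (-1.11) and PTPRZ1 (-0.85) (adjusted p = 0.0813), and blood cell markers in 1 of 9, CD14 (-0.18) (adjusted p = 0.216). The medians of the nuclear-retained, epithelial and glial lists, -0.05, -0.06 and -0.04, turned positive with equal array medians and with quantile normalization, and that of the melanocytic list, -0.07, with equal array medians. TYR and CD14 were each lower in 3 lines and higher in 3 and did not pass with the lines as units (adjusted p = 0.415 and 0.256). The calls of KRT18, CLDN4, TYR and CD14 ended in 29, 27, 26 and 10 of 36 fits without 1 array, and that of KRT7 without the marked probe sets (adjusted p = 0.20).

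Of the 29 lists, camera with the preset correlation called 12, 8 upward and 4 downward. After quantile normalization it also called 12, but 5 upward and 7 downward. With an estimated correlation camera called 0 (3 at an unadjusted p under 0.05), and fry called 22. Adjusted over the list alone, the counts differed from those above in 10 lists: actin filament binding had 21 rises and 3 falls, ribosomal proteins 38 rises, translation factors 32 rises and 1 fall, microtubules 21 rises and 4 falls, mitochondrially encoded genes 4 falls, hypoxia and glycolysis 9 rises and 9 falls, interferon response 4 falls and 0 rises, melanocytic markers 1 rise and 2 falls, and epithelial and blood cell markers 0 of either. In other splits of the arrays the number of called lists was often as high (29 of 100 splits, the real one included), while the largest median change of the ER list in the other splits was 0.55 in size and that of the matrix list 0.56.

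**Figure D3:**
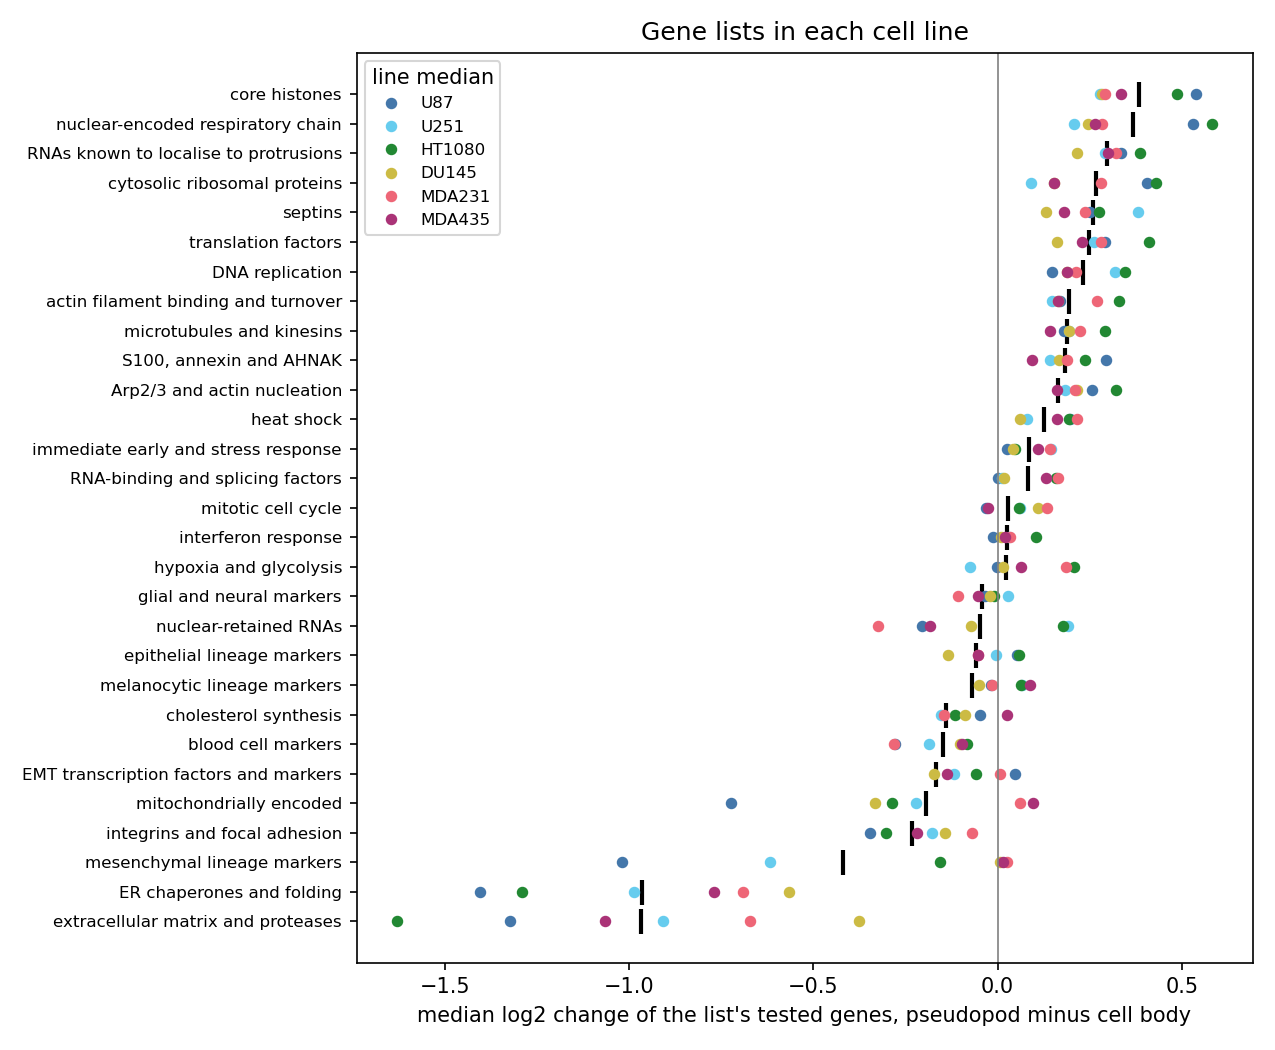
Median log2 change (pseudopod minus cell body) of the tested genes of each list, with a coloured point per cell line and a black mark for the averaged contrast. The ER and extracellular matrix lists lie lowest in the average, at -0.97 each.

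With the 6 lines as units, RNA45SN5 fell by 3.25 ± 0.20 (SE; limma on 6 line differences, adjusted p = 6.09e-05) and SERPINH1 by 1.83 ± 0.13 (adjusted p = 8.02e-05). ESYT1, IL1RAP, CCPG1, B4GAT1, SNORA21, HSPA13, STT3A and RNF149 completed the 10 largest changes, all lower in 6 of 6 lines, with adjusted p from 9.25e-05 for SNORA21 to 0.00039 for STT3A. RAB13 (adjusted p = 0.000716), NET1 (0.00172) and EIF4E (0.025) passed here too. In this fit 4459 genes were higher and 2975 lower in pseudopods; 4101 higher and 2791 lower genes were called in both fits.

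In U87, HINT3 (3.17-fold, log2 1.67 ± 0.38), ROMO1 (2.92-fold) and RPL7AP10 (1.53) were higher in pseudopods, as was APLN, which encodes the secreted peptide apelin (from 12.5 to 64.7 intensity units). POGLUT2, an ER glucosyltransferase, fell 5.37-fold (-2.42 ± 0.29, adjusted p = 3.94e-06), CCPG1 5.19-fold and RNA45SN5 5.02-fold, and the antigen presentation gene HLA-DRA fell 4.80-fold, from 893 ± 106 to 230 ± 218 (SD, n = 3 each). ER chaperones fell in 22 of 27 cases and matrix genes in 32 of 40, and 39 of 61 respiratory genes rose. There were 1801 genes higher and 1807 lower (limma, adjusted p under 0.05). Pseudopod replicate 3 lay nearer to the cell bodies, with RNA45SN5 at 408 against 85.2 and 15.3 in replicates 1 and 2; without it 4437 genes were called, without pseudopod replicate 2 there were 2134, and a fit of the 6 U87 arrays alone called 1417, without RNA45SN5 (adjusted p = 0.0898). With equal array medians there were 2216 higher and 1540 lower genes. The calls of APLN and RNA45SN5 ended without pseudopod replicate 2 (adjusted p = 0.0631 and 0.0617), and that of APLN without cell body replicate 1 (adjusted p = 0.0571) and with the mean of all probe sets (0.139).

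In U251, pseudopods held more of the linker histone transcript H1-3 (3.19-fold, log2 1.67 ± 0.33, adjusted p = 0.000713), ZNF235 (1.26), CENPH (1.25) and EIF4EBP1 (1.17). RNA45SN5 fell 9.32-fold. IQGAP1, a scaffold of the cortical cytoskeleton, fell 6.35-fold, from 1901 ± 288 to 287 ± 54.2 (SD, n = 3 each; adjusted p = 5.92e-06), STT3A 5.74-fold and FRG1BP 4.45-fold. The ER list fell in 19 of 27 cases and the matrix list in 19 of 40, and 4 of 61 respiratory genes rose. The test called 826 genes higher and 1429 lower; without pseudopod replicate 2 it called 1476 in all, and with array weights 4373, 2236 of them higher. The call of ZNF235 ended without pseudopod replicate 1 (adjusted p = 0.0726), pseudopod replicate 2 (0.0691) or cell body replicate 1 (0.0520).

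HT1080 gave the most calls of the 6 lines in the fit of all arrays, 1977 higher and 1844 lower. That total of 3821 was below the 4437 of U87 without U87 pseudopod replicate 3. Its pseudopods were higher in RPL7AP10 (4.20-fold, log2 2.07 ± 0.30), the membrane glycoprotein gene PROM2 (1.99), NUDT14 (1.69) and the chemokine gene CCL20 (from 14.8 to 84.4 intensity units, adjusted p = 0.0282). RNA45SN5 fell 17.6-fold (-4.14 ± 0.56), THBS1 8.91-fold (-3.16 ± 0.34, from 773 ± 101 to 73.0 ± 15.2, SD, n = 3 each; adjusted p = 2.31e-07), ESYT1 8.30-fold and the complement protease gene C1S 7.99-fold. Matrix genes fell in 34 of 40 cases, ER chaperones in 20 of 27, and 42 of 61 respiratory genes rose. With array weights 6168 genes were called, 3649 of them higher. With the replicate number as a block 1361 were higher and 1642 lower, and 1162 and 1717 when at least 1.5-fold was asked for. The balance of higher and lower calls was therefore not stable. The call of CCL20 ended in 5 of 6 fits without 1 array, with adjusted p up to 0.0924, and that of PROM2 without the marked probe sets (adjusted p = 0.386).

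DU145 gave the fewest calls in the fit of all arrays, though not in the fits of each line alone, with 126 higher and 336 lower. Higher in its pseudopods were the RNA STX17-DT (2.92-fold, adjusted p = 0.041), NECAB2 (log2 1.38 ± 0.26), the homeobox gene PRRX2 (1.22 ± 0.13, adjusted p = 3.40e-06) and RPL7AP10 (1.18). RNA45SN5 fell 10.1-fold, SNORA21 4.43-fold, TAF1D, a component of the RNA polymerase I machinery, 4.08-fold (-2.03 ± 0.24), and MIR181A2HG, a microRNA host transcript, 4.06-fold. Only 2 of 27 ER genes and 2 of 40 matrix genes passed as lower, with list medians of -0.57 and -0.38. Calls numbered 168 and 94 without pseudopod replicates 1 and 2, and 90, 228 and 221 without cell body replicates 1, 2 and 3, and CDH1 and EPCAM differed between its arrays. With the epithelial covariate, which alters the spread and not the changes, 1219 genes were called. A fit of the 6 DU145 arrays alone called 1304 genes, equal array medians gave 145 higher and 151 lower and array weights 1570 and 1725, so the excess of lower genes was not stable. The calls of STX17-DT and RPL7AP10 ended in 6 and 5 of 6 fits without 1 array, with adjusted p up to 0.172 and 0.144.

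In MDA231, UBALD1 was 2.70-fold higher in pseudopods (log2 1.43 ± 0.19, adjusted p = 8.26e-05), followed by the zinc finger genes KLF16 (1.23) and ZNF668 (1.21) and by TRIM52-AS1 (1.08). RNA45SN5 fell by 3.70 ± 0.56 on the log2 scale, MIRLET7D, a microRNA locus, 4.31-fold, TAF1D 3.94-fold (-1.98 ± 0.24, adjusted p = 4.19e-05) and PABPC1L 3.49-fold. The ER and matrix lists each had 6 fallers, of 27 and 40 genes, and medians of -0.69 and -0.67. There were 181 genes higher and 747 lower, but 541 higher and 369 lower with equal array medians and 1863 and 2270 with array weights, so the excess of lower genes was not stable. A limma fit of the 6 MDA231 arrays alone called 0 genes (2154 at an unadjusted p under 0.05), and leaving out 1 array gave 428, 246 and 1308 without pseudopod replicates 1, 2 and 3 and 332, 1349 and 460 without cell body replicates 1, 2 and 3. CDH1 and EPCAM differed between the arrays. With the epithelial covariate, which alters the spread and not the changes, 1869 genes were called. The calls of KLF16, TRIM52-AS1, ZNF668 and PABPC1L ended in 5, 4, 2 and 2 of 6 fits without 1 array, with adjusted p up to 0.185, 0.127, 0.119 and 0.0884. With the mean of all probe sets KLF16 changed by 0.51 and TRIM52-AS1 by 0.50 (adjusted p = 0.328 and 0.217), and without the marked probe sets PABPC1L changed by -0.31 (adjusted p = 0.248), so these calls ended too.

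In MDA435, PLEK2, a pleckstrin family gene (3.09-fold, log2 1.63 ± 0.35), UBALD1 (1.44 ± 0.19), PROM2 (1.41; -0.16 without the marked probe sets) and FKBP8, a mitochondrial outer membrane protein gene (1.23; 0.38 with the mean of all probe sets, adjusted p = 0.165), were higher in pseudopods. RNA45SN5 fell 6.78-fold. Fallers included the matrix proteoglycan gene VCAN (6.23-fold), PTPRZ1, a receptor phosphatase of neural cells (5.72-fold, -2.52 ± 0.23, adjusted p = 6.44e-08), and PCOLCE, an enhancer of procollagen processing (5.41-fold). Matrix genes fell in 19 of 40 cases and ER chaperones in 11 of 27. The test called 453 genes higher and 1346 lower; CDH1 and EPCAM differed between the arrays, 1038 genes were called without pseudopod replicate 2, 725 in a fit of the 6 MDA435 arrays alone and 5001 with array weights, 2478 higher and 2523 lower. The call of PROM2 ended in 5 of 6 fits without 1 array, with adjusted p up to 0.144, and that of PCOLCE in the fit of the line alone (adjusted p = 0.130).

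The lines differed in the pseudopod change of 159 genes (moderated F test of the fraction by line interaction; 1515 at an unadjusted p under 0.05), 143 of which were also called in the average. NID1, a basement membrane glycoprotein gene, fell by 2.27 ± 0.15 in HT1080, 1.04 in U251 and 0.76 in DU145, and stood below 10 intensity units in the other 3 lines (interaction adjusted p = 7.78e-07). ANPEP, a surface aminopeptidase gene, fell by 2.17 in HT1080, from 2037 to 450.1, and was at most 7 in the other lines (adjusted p = 1.35e-05); TRHDE, another peptidase gene, fell by 1.74 in HT1080 from 601 to 169 and was at most 5.33 elsewhere. PDCD1LG2, which encodes the immune ligand PD-L2, fell by 1.46 in U87, from 39.1 to 4.13, and was at most 2.83 in the other lines. CHST6, a sulfotransferase gene, fell by 1.71 in MDA435, from 79.8 to 14.4, and was at most 3.27 elsewhere. Lines in which a gene is this dim cannot show its fall. MCOLN3, a lysosomal channel gene, fell in HT1080 (-1.83), MDA435 (-1.58), MDA231 (-1.18) and DU145 (-1.15), whereas it changed by 0.33 in U87 (adjusted p = 0.203) and 0.08 in U251 (adjusted p = 0.856) at 6.03 to 14.5 intensity units. The count was 769 without U87 pseudopod replicate 3 and 102 without HT1080 cell body replicate 2. As many genes were called in 11 of 100 splits of the arrays, the real one included, but such splits can turn a shared change into an interaction. It was 19 with a pseudocount of 1, where ANPEP and TRHDE did not pass (adjusted p = 0.855 and 0.879; ANPEP had 0.0537 with the mean of all probe sets), and 2326 with array weights.

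Across genes, the changes of any pair of lines went together, with Pearson correlations from 0.67 to 0.84 and Spearman correlations from 0.58 to 0.78 over 15 pairs that share no arrays; genes are not independent replicates. The changes had the same sign in 70.2% to 78.5% of genes. RNA45SN5 was among the 160 genes called lower in all 6 lines, and 11 genes were called higher in all 6. The size of the change differed: the slope of a line's changes on the mean of the other lines was 1.37 in HT1080, 1.19 in U87, 0.89 in U251, 0.89 in MDA435, 0.71 in MDA231 and 0.63 in DU145, where the 3 pseudopod arrays of U87 gave 1.33, 1.62 and 0.63. Opposite calls between lines were made for 10 genes.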

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

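The tests of whole arrays swapped between lines, of the balance of the splits and of each list's median in the splits were chosen only after the result was seen.

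In 34 tests of a gene or slope for a cell line far from the other 5, 4 gene values stood apart, 1 in U87 and 3 in HT1080, against 1.7 expected by chance at 1 in 20. HINT3 changed by 1.67 in U87. MYBL2 changed by 1.16 in HT1080. ESYT1 changed by -3.05 and ALG1 by -2.79 in HT1080. This outlier test uses the 6 line means and leaves out the spread between arrays. None of these genes passed the moderated F test of the interaction (adjusted p = 0.569 for ESYT1, 0.701 for ALG1, higher for HINT3 and MYBL2). They are therefore not shown to differ between lines.

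Differences between lines passed the interaction test for 17 of the named genes. The adjusted p was 7.78e-07 for NID1, 1.86e-06 for PDCD1LG2, 4.33e-06 for CHST6, MCOLN3 and TRHDE, and 1.35e-05 for ANPEP. PTPRZ1 (5.76e-05) fell in MDA435 (-2.52), U251 (-1.45) and HT1080 (-0.63), and was at most 13.9 intensity units outside MDA435 and U251. CDH2 (0.000456) fell in HT1080 (-2.27), MDA435 (-1.90), U87 (-1.79) and U251 (-1.34), and at 2.83 to 11.6 intensity units in DU145 and MDA231 it was too dim to show a fall. PRRX2 (0.000456) rose by 1.22 in DU145, and UBALD1 (0.000943) rose by 1.43 in MDA231 and 1.44 in MDA435. MIR181A2HG (0.00600) fell in DU145 (-2.02), U251 (-1.63) and HT1080 (-0.84), and was at most 11.7 intensity units in U87, MDA231 and MDA435. TYR (0.00926) fell by 1.40 in MDA435, from 605 to 215, and stood at only 27.2 to 50.4 in the other lines, where there was less signal to lose. VCAN (0.0110) fell in HT1080 (-2.97), MDA435 (-2.64) and U87 (-2.14) and was at most 22.5 in DU145 and MDA231. HLA-B (0.0170) fell in HT1080 (-2.01), U87 (-1.19), MDA435 (-1.16) and U251 (-0.72). COL5A2 (0.0257) fell in MDA435 (-2.23), U87 (-2.14) and U251 (-1.16), and stood at 37.4 to 62.3 in HT1080, DU145 and MDA231. THBS1 (0.0276) fell in HT1080 (-3.16), MDA435 (-1.98), U87 (-1.15) and U251 (-1.03). POGLUT2 (0.0414) fell in U87 (-2.42), HT1080 (-2.18), U251 (-1.98) and MDA435 (-1.34).

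Epithelial genes differed between replicate arrays of MDA231 and MDA435. Genes bright in DU145 rose with CDH1 in MDA435 at a median of 0.0134 of the DU145 proportion (93 genes, upper quartile 0.148), which argues against DU145 cells as the whole source, and 0 of 36 arrays correlated best with another line, which argues against whole arrays swapped between lines. Over 3649 genes dim in both lines, the slopes on CDH1 in MDA231 and MDA435 had r = 0.839 across genes (Spearman 0.446; genes are not independent replicates), against 0.217 for MDA231 and DU145. This is consistent with one further epithelial cell type in both cultures, and genes that rose with CDH1 in both include ABCB1, up to 1370 in MDA231 and 1259 in MDA435, and TMEM200A, up to 1637 and 1142. A change of state of the lines' own cells stays open, as untested.

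U87 pseudopod replicate 3 lay near the cell body arrays, with r across genes of 0.982 with the cell body mean and 0.972 with the mean of pseudopod replicates 1 and 2. A swap with a cell body array needs a cell body array near the pseudopods, and 0 of 3 were. The share of cell body signal was 0.431 ± 0.013 from genes that fall and 0.53 ± 0.021 from genes that rise in the other lines (bootstrap SD). Cell body material in that array predicts equal shares. The difference of -0.095 was under the limit set beforehand for that explanation, but larger than the bootstrap SDs. A pseudopod change that was weaker in that culture by a similar share in all genes predicts equal shares too. The test cannot tell the 2 explanations apart, and both stay open.

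Other splits of the arrays gave as many genes as the averaged contrast in 1 of 100, the real one (7737 genes, highest other 2210). With the lines as units, exchanging fractions of whole lines gave 7434 calls or more in 1 of 32, the real one (highest other 0). Both shares are under 0.05, but each is the smallest that its number of splits allows. The splits of arrays also treat the arrays of a line as independent, which the labels do not state. For a single line there are only 10 splits, too few for a share under 0.05. The real and highest other counts were 3608 and 1582 in U87, 2255 and 5 in U251, 3821 and 2 in HT1080, 462 and 7 in DU145, and 1799 and 1274 in MDA435. In MDA231 3 of 10 splits gave as many (928; highest other 1442).

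In 11 of 100 splits, the real one included, the interaction test called at least as many genes (159 in the real split, highest other 1604). A split that follows the fractions in some lines and reverses them in others turns a change shared by the lines into an interaction. The splits therefore cannot say how often chance alone gives 159 genes, and chance is not excluded for the interaction. Chance is not excluded for the number of called lists either, with 29 of 100 splits as large, the real one included (12; highest other 17). Of the 64 splits in which the numbers of pseudopod and cell body arrays within a group of 18 differ by at most 2, 13 called as many lists, and the highest averaged gene count among them was 1. The medians of the ER, matrix, respiratory and ribosomal lists lay farther from 0 in the real split than in any other of the 100. The same held for most lists, including the septin, cholesterol synthesis and blood cell lists, which camera did not call. Medians of the mitotic, hypoxia, interferon and epithelial lists were matched by 70, 70, 80 and 71 of 100 splits, the real one included.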

How the results depend on the processing

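Pseudocounts of 1 and 64, the fits without 2 or 3 lines, the epithelial covariate and the fit of the lines as units and of the lists without U87 pseudopod replicate 3 were tests chosen only after the result was seen. The RNA quality covariate and the tests of 3-prime to 5-prime ratios and spike-in levels were not run, since the table holds 0 control probe sets. Of 8041 alternative values for 192 results of named genes, 7817 kept their sign and side of the threshold. Another 210 no longer passed, 7 newly passed and 7 changed sign. A gene counts once for each line or contrast in which it was named. Many of these values come from fits without 1 array, which share most arrays with the main fit. Of 433 values for 29 lists, 379 kept sign and side, 17 no longer passed, 23 newly passed and 14 changed sign. The averaged contrast called 8850 genes with equal array medians and 7998 with quantile normalization, of which 7056 and 7025 were among the 7737.

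The cause of the following differences was not tested, except that testing every probe set, asking for 1.5-fold and leaving out arrays or lines change what is tested. Camera with an estimated correlation called 0 lists and fry 22. Equal array medians gave 296 genes in DU145, and the mean of all probe sets 744. Every probe set gave 17518 calls in the average, 16393 with the lines as units, 7342 in U87, 5121 in U251, 8009 in HT1080, 2315 in DU145, 3026 in MDA231, 4262 in MDA435 and 436 for the interaction. Array weights gave 4373 in U251, 6168 in HT1080, 3295 in DU145, 4133 in MDA231, 5001 in MDA435 and 2326 for the interaction. Replicate numbers did not pair the fractions (4 of 18 pairs with r over 0.1). Some pseudopod arrays went with a cell body array of another number, such as MDA435 replicate 1 with 3 (r = 0.769) and 3 with 1 (0.794) and MDA231 replicate 3 with 2 (0.814), and the block by number does not pair these. As a block the numbers gave 7042 in the average, 130 in DU145, 461 in MDA231 and 35 for the interaction. At least 1.5-fold left 1876 in the average and 1869 with the lines as units. The 6 arrays of a line alone gave 1417 in U87, 1304 in DU145, 0 in MDA231 (2154 at an unadjusted p under 0.05, limma) and 725 in MDA435. A pseudocount of 1 gave 295 in DU145 and 19 for the interaction, and 64 gave 768 and 398. The interaction had 264 genes without MDA231 and MDA435, and the lines as units 4866 without DU145, MDA231 and MDA435. The epithelial covariate gave 1219 in DU145, 1869 in MDA231 and 448 for the interaction. It left the changes as they were, and calls also rose in the lines without a slope, to 4594 in U87, 3341 in U251 and 4935 in HT1080.

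Without 1 array the counts ran from 7475 to 7966 in the average, 2134 to 4437 in U87, 1476 to 1947 in U251, 2764 to 3285 in HT1080, 90 to 341 in DU145, 246 to 1349 in MDA231, 1038 to 1965 in MDA435 and 102 to 769 for the interaction. The lines as units gave 5523, 5946 and 5141 without replicate 1, 2 or 3 of every group and 7298 without U87 pseudopod replicate 3, and the lists stayed at 12 without U87 pseudopod replicate 3.

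Signs turned for GAPDH with quantile normalization (-0.0248), and without probe sets shared between transcripts for PROM2 in MDA435 (-0.16), COL6A1 (0.13), MCM4 (-0.0215) and KLF2 (-0.0231). TYR was at 0.0128 without MDA231 and MDA435 and 0.0821 without DU145 too. List medians that turned were, with equal array medians, nuclear-retained RNAs 0.0498, epithelial 0.0392, melanocytic 0.0283 and glial markers 0.0544. With quantile normalization they were nuclear-retained RNAs 0.0272, hypoxia -0.0176, epithelial 0.00204 and glial 0.0274. With the mean of all probe sets splicing factors were at -0.0746 and mitotic genes at -0.0260, and with array weights hypoxia at -0.0337. Nuclear-retained RNAs were at 0.0320 without MDA231 and MDA435, and at 0.0893 without DU145 too, where epithelial markers were at 0.0101. Dim genes are limited by signal over background, since 42.8% of pseudopod and 40.3% of cell body values were at or below 16.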

Other observations

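The families of genes and the tests of array scaling, of longer gene spans and of the place of translation were chosen only after the result was seen. Families of membrane and secretory pathway proteins fell beyond the lists. Of 260 solute carrier genes other than the mitochondrial SLC25 group, 159 fell and 13 rose (median -0.42), led by the zinc transporter genes SLC39A10 (-1.70) and SLC39A7 (-1.67). Of 42 glycosyltransferase genes 35 fell and 2 rose, with GALNT7 at -1.45, and of 21 genes for synthesis of the GPI anchor 16 fell and 1 rose, with PIGO and PIGK at -1.48 each. TMEM genes fell in 105 of 190 cases and rose in 20. Semaphorin and protocadherin genes fell in 32 of 48 cases, with SEMA4C at -1.35, receptors for TNF and interleukins in 33 of 57, tetraspanins and TM9SF in 15 of 25, and ADAM proteases in 14 of 26. Camera with an estimated correlation gave adjusted p = 0.0125 for the solute carriers and 0.0196 for the ADAM proteases, the highest of these 8 families.

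In 7 families of proteins made in the cytosol risers outnumbered fallers, but 5 of them, the 3 mitochondrial ones included, missed the threshold of camera with an estimated correlation. Of 76 mitochondrial ribosomal protein genes 72 rose and 0 fell (median 0.45), with MRPL40 at 0.75, and of 24 LSM and SNRP genes for RNA splicing and decay 22 rose and 0 fell (median 0.53), with LSM5 at 0.90. Proteasome genes rose in 29 of 37 cases and fell in 2, ubiquitin-conjugating enzymes in 23 of 29 with 1 fall, mitochondrial import genes in 17 of 21, RNA polymerase subunits in 19 of 32 with 1 fall, and SLC25 carriers in 19 of 45 with 2 falls. With an estimated correlation camera gave adjusted p = 0.0125 for ubiquitin-conjugating enzymes and 0.0406 for the LSM and SNRP genes. The other 5 ran from 0.050 for mitochondrial ribosomal proteins to 0.159 for the proteasome. The medians of all 15 families kept their sign with equal array medians and with quantile normalization. The families were not compared with genes of similar intensity.

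Genes for the ER and matrix were lower and those for respiration and ribosomes higher, in a pattern that quantile normalization did not remove: the difference between these pairs of list medians was then 1.20, against array scaling as the cause, and it was 1.23 among genes over 1000 intensity units, against a distortion of dim values. ER and matrix genes with a span of at most 10 kb lay at -0.88 from other genes of that span (17 genes). For 50 genes of longer span the difference from genes of similar span was -1.06. The span bounds the transcript length only from above, and transcript lengths were not used here. A loss of long transcripts therefore cannot be told apart for either group. The medians of 0 of the 8 families translated at the ER reached the lowest of the 7 families translated in the cytosol. A candidate explanation is that transcripts translated at the ER stay in the cell body with it, a hypothesis found and tested on the same data. It does not account for genes of proteins made in the cytosol that fell, such as IQGAP1 (-1.72), AHNAK (-1.52), ASPM (-0.92), ANLN (-0.82), VCL (-0.81), DYNC1H1 (-0.72), DIAPH1 (-0.62) and ACTN4 (-0.54).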
